A study of Gallus gallus with 8 samples.

How the data were processed

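RNA was measured in cells sorted from the neural tube of chick embryos of the white Leghorn breed. Per the labels' protocols, embryos at Hamburger and Hamilton stages 10 to 11 were electroporated in ovo with 2 plasmids. One carried enhanced green fluorescent protein behind a BMP-responsive element (BRE), a DNA sequence that drives transcription when bone morphogenetic protein signalling is active. The other carried a nuclear red fluorescent protein that marks every electroporated cell. Neural tubes were dissected 24 h later, nearly 30 embryos were pooled, and red cells were sorted into a green fraction (BRE_active) and a fraction without green (BRE_inactive). The same was done for 4 pools, which gives 4 arrays per group and 8 in all. Per the labels, each pool gave at least 100000 red and 20000 green cells. Biotinylated cRNA was made by the standard Affymetrix protocol, per the labels. The pools were separate sets of embryos, so the spread between arrays of a group includes differences between embryo pools.

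The authors deposited log2 expression values, 1 per probe set and array, for 38535 probe sets, with group means, SDs, a log2 difference, an adjusted p-value and the number of arrays of each group on which a probe set was called present, marginal or absent. The background correction, the between-array normalization, the summary of probes and the caller behind the present calls are not given in the sources used here. A second deposited set of log2 values was the same within 1e-08. The authors' deposited adjusted p-value was obtained again from a limma fit on group alone over all probe sets, with a largest difference of 6.13e-13. The 8 columns that hold the present, marginal or absent letter of each array were not used. Array medians lay between 4.24 and 4.32 on the log2 scale, and pairs of arrays correlated between 0.974 and 0.996. No 2 arrays held the same values, the smallest SD of a difference between 2 arrays being 0.192. The precision is limited by the number of arrays.

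The 96 Affymetrix control probe sets were left out, and 38439 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, Benjamini-Hochberg adjustment, threshold 0.05). All differences are BRE_active minus BRE_inactive on the log2 scale, with the standard error of the limma fit, from 4 arrays in each group. Gene names in the deposited table are old, so symbols were updated through the Entrez gene ID with a RefSeq gene table of assembly GRCg7b. Of 26142 probe sets with a gene ID, 22925 matched, and the table's own symbol was kept otherwise. The update changed the meaning of some names: the probe set called OLIG3 in the deposited table is OLIG2 by its gene ID, and that called WNT3 is WNT3A. No symbol was attached to 13646 of the tested probe sets. A gene was represented by the probe set with the highest mean over the 8 arrays, which gave 13249 genes. The build behind the deposited table is not given in the sources used here, and no coordinates are printed.

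A group of arrays on which a probe set was present on none has only a bound. Where such a gene is given as "at least N-fold", the mean of the brighter group was set against the mean, per array, of the higher of the probe set's own value and the lowest value among probe sets present on all 4 arrays of that group. For the genes so given this equals the fold of the measured difference. It bounds only the undetected level and does not take in the standard error or the spread between arrays.

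The 25 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 12 genes with the largest increase and the 12 with the largest decrease among called genes that had 1 sign in all 4 pools and whose brighter group lay above the median of probe set means, leaving out symbols that are only LOC or open reading frame numbers. It adds up to 4 members of each list with the smallest p, and 25 genes named in any case, of which 23 were measured (LMX1A and ATOH1 had no probe set under their symbols). This gave 127 genes, a few of which are not reported here. Lists were tested with camera (preset inter-gene correlation 0.01, two-sided), with adjustment over the 25 lists, and also with camera with an estimated correlation and with fry. Older symbols in the lists were accepted only where the gene table gives them as a synonym. This rule was tightened after first results had been seen, because the looser one had matched wrong genes. It changed 10 of 521 list entries, and the same 12 lists were called under both rules. No annotation terms came with the probe sets used here, so the planned term enrichment was not run.

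The replicate number is the pool of embryos, and both fractions of a number came from the same embryos, so the numbers pair the arrays by design. The deviations of same-numbered arrays from their group means correlated at -0.141, 0.203, 0.498 and 0.584 in pools 1 to 4, and the consensus correlation within pools was 0.223. The fit with the pool as a block was run beside it, and its value is given where it changes a call or moves a count by over 1.5 times. Also fixed in advance were a random block, quantile normalization or median centring on top of the deposited values, a trend and robust prior, a filter on dim probe sets, array weights, the mean of a gene's probe sets, stricter thresholds, and leaving out each pool and each array. Added after the data were seen were a covariate for the leading axis of the within-group deviations, a filter on present calls, leaving out 3 arrays that stood apart, and an estimated correlation for the somite and mesoderm list without BRE_active 1.

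The fit was tested on simulated data with the real means and spreads of the 38439 probe sets for BRE_active against BRE_inactive, with 50 probe sets changed at each of 4 sizes. It recovered 36% of 1.5-fold, 66% of 2-fold, 90% of 3-fold and 96% of 4-fold changes, with 5 false calls among 149. With no change simulated it made 0 calls. The changed probe sets were drawn only from those above the median of probe set means. The simulated noise was independent between arrays and between probe sets. It held neither pools nor the leading axis of the real arrays, so these rates need not hold for the real data. Smaller differences can therefore be missed with 4 arrays per group.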

Results

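Genome-wide expression was measured in 8 arrays of sorted chick neural tube cells, 4 from cells with an active BMP reporter (BRE_active) and 4 from cells of the same embryo pools in which the reporter was silent (BRE_inactive). The study, by its title, concerned the delamination of neural crest cells and the inhibition of Wnt signalling by DACT1 and DACT2. The comparison asks which genes differ between neural tube cells that respond to BMP and those that do not. Of the 38439 probe sets, 12187 (31.7%) were called present on all 4 BRE_active arrays and 11482 (29.9%) on all 4 BRE_inactive arrays, while 18320 (47.7%) were present on no array.

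The largest increases in cells with an active reporter included genes of the neural crest and dorsal neural tube, and the largest decreases included globins. The 12 largest increases were LTK, a receptor tyrosine kinase, TFAP2B, SNAI2, EDNRB, DLC1, WNT3A, FOXD3, COL9A3, SOX10, UNC5C, PPP1R1C and SOX5. They ranged from a log2 difference of 1.92 ± 0.31 (SE, 4 arrays per group) for SOX5 to 2.63 ± 0.34 for LTK, whose adjusted p was 0.00351. DLC1, which encodes a GTPase-activating protein, rose by 2.07 ± 0.16 (adjusted p = 0.000274). COL9A3, a collagen IX chain, rose by 2.03 ± 0.20 (adjusted p = 0.000974). UNC5C, a netrin receptor, rose by 1.97 ± 0.27 (adjusted p = 0.00396), and PPP1R1C, an inhibitor of protein phosphatase 1, by 1.95 ± 0.20 (adjusted p = 0.00117). The 12 largest decreases included HBBA, HBZ, HBBR, TSPO2, HBAD, SLC4A1, SLC25A37, TUBB1, HBA1, LGALSL2 and HBB, most of them genes of red blood cells, with differences from -2.97 ± 0.59 for HBB to -5.83 ± 0.94 for HBBA.

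In all, limma called 517 probe sets at an adjusted p under 0.05, 377 higher and 140 lower in BRE_active cells, and each of the 517 had 1 sign in all 4 pools. At the gene level 397 of 13249 genes were called, 267 higher and 130 lower, and 169 of them differed by at least 2-fold. With the pool of embryos as a block, which pairs the arrays, 2156 probe sets (1527 higher, 629 lower) and 1215 genes (777 higher, 438 lower) were called. The counts also depended on single pools and arrays: leaving out 1 pool gave 77 (pool 3) to 1269 (pool 4) probe sets and 135 to 719 genes, and leaving out 1 array gave 211 (BRE_active 3) to 1419 (BRE_active 4) probe sets and 223 to 809 genes. The mean difference between 3-prime and 5-prime signal of 3 control genes was larger in BRE_active cells in all 4 pools, by 0.334 on average on the log2 scale.

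**Figure D1:**
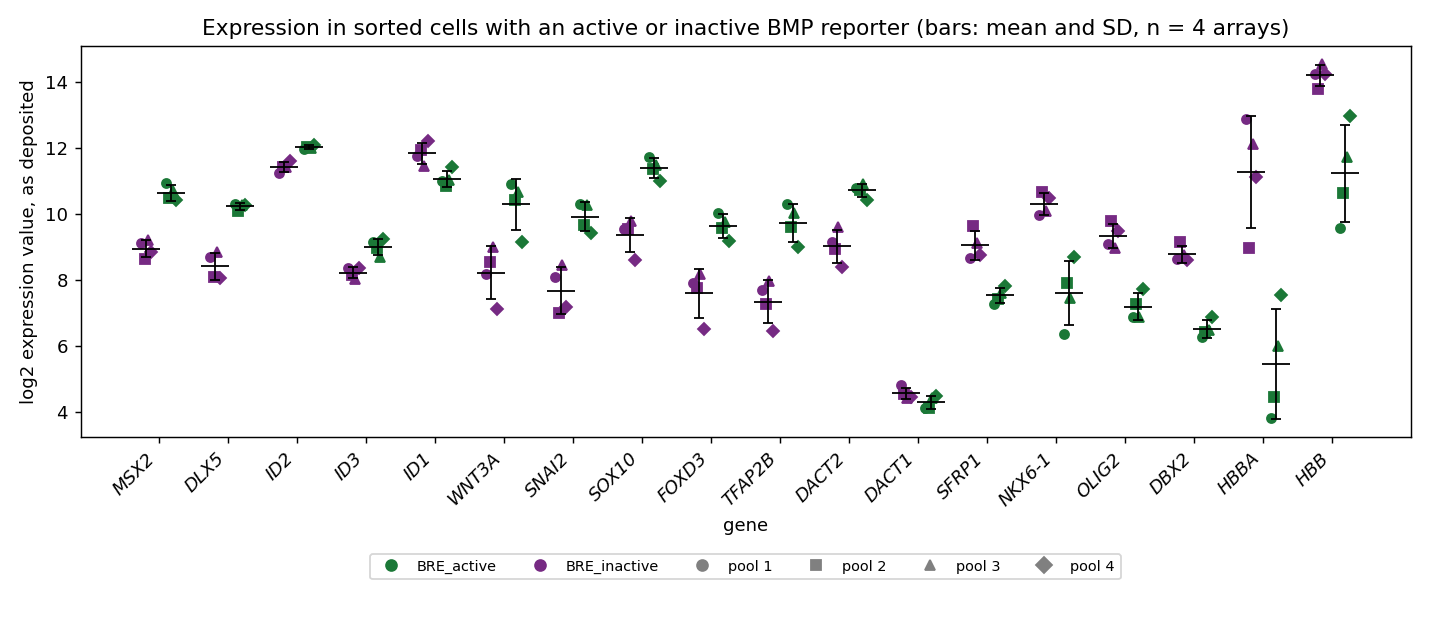
Log2 expression values of 18 genes (x axis) on each of the 8 arrays (y axis, log2 as deposited). Each point is an array, colour gives the reporter state, shape the embryo pool, and black bars the mean and SD of 4 arrays. MSX2 and DLX5 lie higher on all 4 BRE_active arrays, while NKX6-1, OLIG2 and the globins HBBA and HBB lie lower.

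BMP response genes were higher as a group by camera (adjusted p = 7.7e-06), though the adjusted p = 0.0522 with an estimated correlation was not past the threshold. Of 19 measured members, 7 rose, 1 fell and 11 were not called, and adjusted over the list alone 9 rose and 1 fell. The homeobox genes MSX2, DLX5 and MSX1, which are direct BMP targets in many tissues, rose by 1.69 ± 0.15 (adjusted p = 0.000584), 1.81 ± 0.18 (adjusted p = 0.000974) and 0.93 ± 0.14 (adjusted p = 0.00728). Among the inhibitors of DNA binding, ID2 rose by 0.60 ± 0.09 (adjusted p = 0.00728) and ID3 by 0.79 ± 0.13 (adjusted p = 0.0122). ID1 went the other way, from 11.85 ± 0.33 (SD, n = 4) in BRE_inactive to 11.08 ± 0.24 in BRE_active cells, a difference of -0.76 ± 0.17 (adjusted p = 0.0487), with 1 sign in all 4 pools. The inhibitory SMAD genes were not called: SMAD6 differed by 0.82 ± 0.23 (adjusted p = 0.106, 0.00187 with the pool as a block), and SMAD7 was present on 3 BRE_active and 0 BRE_inactive arrays (adjusted p = 0.242).

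Among BMP ligands, receptors and extracellular modulators, 2 of 17 measured members rose and 15 were not called, and 4 rose when adjusted over the list alone. With the block 5 rose and 1 fell. Camera gave the list an adjusted p of 0.00938, and the adjusted p = 0.315 with an estimated correlation. The ligand BMP5 rose by 1.55 ± 0.18 (adjusted p = 0.0019) and BMP7 by 1.37 ± 0.31 (adjusted p = 0.0499). Other, dimmer probe sets of BMP7 gave 0.32 ± 0.09 and 0.04 ± 0.12 (adjusted p = 0.137 and 0.908). The difference of BMP7 was 2.51, 0.764, 1.04 and 1.16 in pools 1 to 4. Over the alternative settings it ranged from 0.578 to 1.6, with adjusted p up to 0.188. The receptor BMPR1B differed by 0.59 ± 0.15 and TWSG1 by 0.54 ± 0.15, with adjusted p = 0.0872 and 0.102, which became 0.0236 and 0.0216 with the block.

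Genes of the dorsal neural tube and roof plate were higher in BRE_active cells by camera (adjusted p = 1.71e-07), with the adjusted p = 0.0695 with an estimated correlation. Of 18 measured members, 7 rose and 11 were not called, 9 rose when adjusted over the list alone, and 11 rose with the block. MSX1, MSX2 and BMP7 are among the members that rose, and they belong to the BMP lists above too. The rise of this list is therefore not fully separate from that of the BMP lists. RSPO3, a secreted enhancer of Wnt signalling, rose by 1.67 ± 0.21 (adjusted p = 0.00351). The Wnt ligand WNT3A rose by 2.07 ± 0.45 (adjusted p = 0.0384), while its other probe set gave 2.23 ± 0.50 (adjusted p = 0.0712, 0.000387 with the block). LMX1B was present on 3 BRE_active arrays and on 0 BRE_inactive arrays and was at least 2.13-fold higher (adjusted p = 0.0124). PAX7 differed by 1.06 ± 0.46 (adjusted p = 0.278, 0.00208 with the block), or by 0.64 without BRE_inactive 4 (adjusted p = 0.504). PAX3 and WNT1 were called present on 0 arrays, with adjusted p = 0.768 and 0.429.

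Neural crest genes were higher as a group by camera (adjusted p = 5.5e-08), with the adjusted p = 0.0522 with an estimated correlation. Of 28 measured members, 10 rose, 0 fell and 18 were not called, and 14 rose and 1 fell when adjusted over the list alone, as with the block. SNAI2, a zinc finger repressor of cadherin genes, rose from 7.69 ± 0.70 to 9.92 ± 0.44 (SD, n = 4), a difference of 2.23 ± 0.33 (adjusted p = 0.00705). The transcription factors FOXD3, SOX10, TFAP2B and SOX5 rose by 2.05 ± 0.33, 2.03 ± 0.25, 2.38 ± 0.35 and 1.92 ± 0.31, with adjusted p = 0.00976, 0.00274, 0.00596 and 0.00938. EDNRB, an endothelin receptor, rose by 2.11 ± 0.22 (adjusted p = 0.00117), and LMO4 by 1.12 ± 0.13 (adjusted p = 0.00203). SOX9, present on 1 BRE_active array and 0 BRE_inactive arrays, was not called (adjusted p = 0.0537), and was called higher with the block (adjusted p = 0.000556). With so few present calls, no size of its difference is given.

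Of 28 measured genes for epithelial-mesenchymal transition, matrix and adhesion, 4 rose and 24 were not called, 7 rose when adjusted over the list alone, and 10 rose with the block. Camera gave the list an adjusted p of 7.5e-05, and the adjusted p = 0.315 with an estimated correlation. The members that rose encode matrix proteins and an integrin: the collagen genes COL9A1 (1.39 ± 0.11, adjusted p = 0.000274) and COL1A2 (0.83 ± 0.18, adjusted p = 0.0446), the basement membrane gene NID1 (1.45 ± 0.27, adjusted p = 0.0202) and the integrin ITGB3 (1.39 ± 0.20, adjusted p = 0.00538). A second well-detected probe set of COL1A2 passed only with the block (0.82 ± 0.245, adjusted p = 0.185, 0.00524 with the block), as did a dim one of ITGB3 that was present on 4 BRE_active and 0 BRE_inactive arrays (adjusted p = 0.152, 0.0466 with the block).

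**Figure D2:**
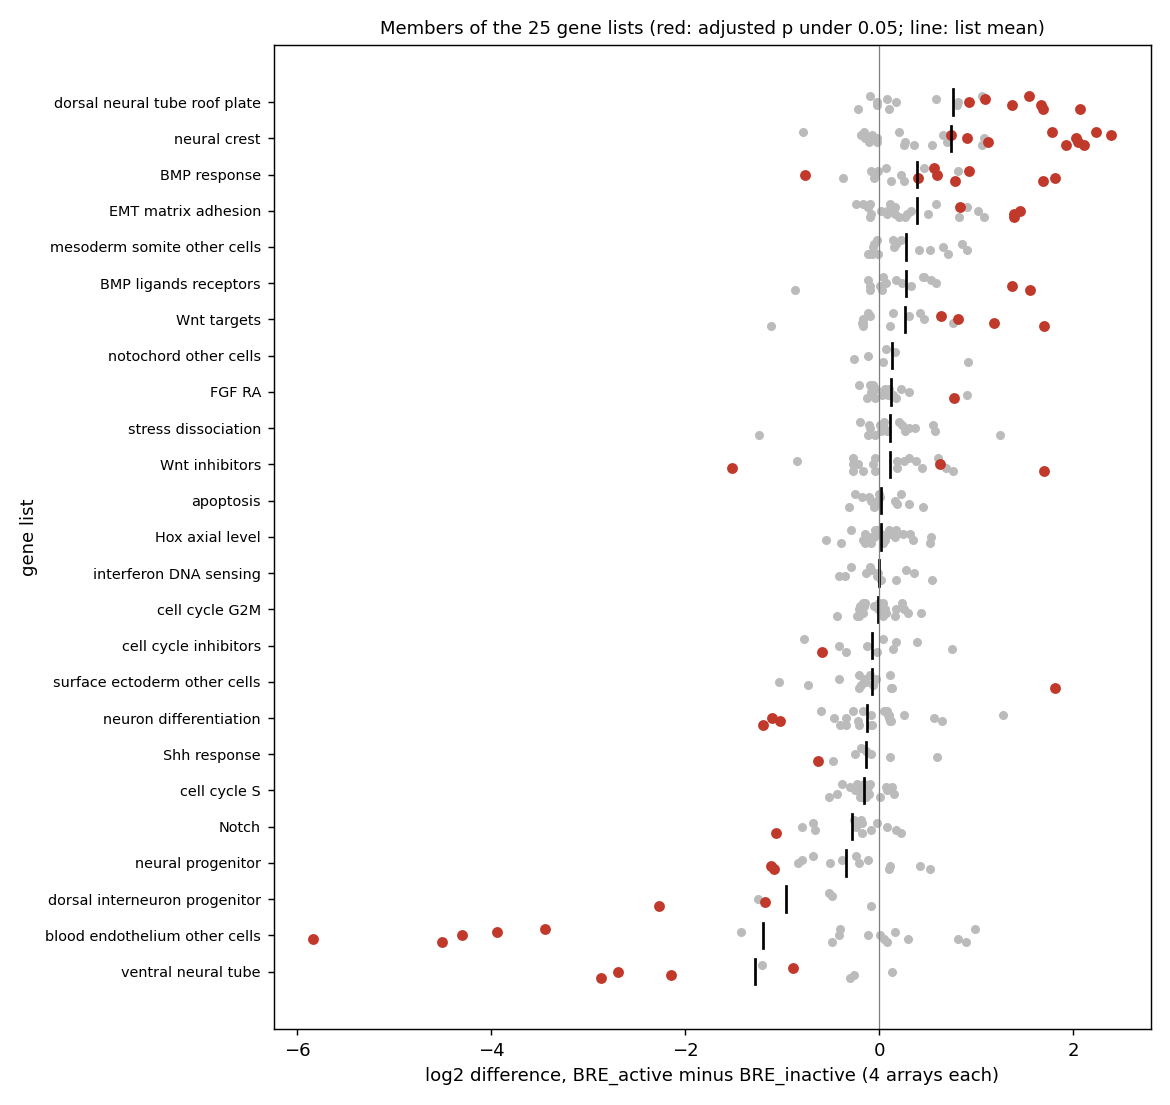
Log2 difference, BRE_active minus BRE_inactive (x axis), of each measured member of the 25 gene lists (y axis), from 4 arrays per group. Red points have an adjusted p under 0.05, grey points do not, and black lines mark list means. The means run from -1.28 for ventral neural tube genes to 0.76 for dorsal neural tube and roof plate genes.

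Wnt target genes were higher in BRE_active cells by camera (adjusted p = 0.0104), with the adjusted p = 0.0975 with an estimated correlation. Of 17 measured members, 4 rose and 13 were not called, adjusted over the list alone 6 rose and 1 fell, and with the block 5 rose and 1 fell. NOTUM and APCDD1, which encode feedback inhibitors of Wnt signalling, rose by 1.70 ± 0.22 (adjusted p = 0.00342) and 1.19 ± 0.18 (adjusted p = 0.00721). The receptor FZD10 rose by 0.81 ± 0.15 (adjusted p = 0.0177) and MYC by 0.64 ± 0.13 (adjusted p = 0.0329). AXIN2 differed by 0.76 ± 0.26 (adjusted p = 0.183, 0.0114 with the block), and LEF1 by 0.42 ± 0.12 (adjusted p = 0.105).

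The Wnt inhibitors moved in both directions. Of 21 measured members, 2 rose, 1 fell and 18 were not called, 2 rose and 2 fell when adjusted over the list alone, 4 rose and 2 fell with the block, and the camera adjusted p was 0.412. DACT2 rose from 9.03 ± 0.50 to 10.73 ± 0.21 (SD, n = 4), a difference of 1.70 ± 0.22 (adjusted p = 0.00364), with 1 sign in all 4 pools. DACT1 was called present on 0 of 8 arrays (adjusted p = 0.289), so no difference in its level is given. The study names both genes in its title, so DACT2 is not independent evidence of a direction of this list. The secreted inhibitor SFRP1 fell, with a difference of -1.52 ± 0.21 (adjusted p = 0.00439), while its other probe set gave -1.10 ± 0.23 (adjusted p = 0.0563, 0.0182 with the block). FRZB rose by 0.62 ± 0.11 (adjusted p = 0.0158). The corepressor TLE4 differed by -0.85 ± 0.21 (adjusted p = 0.0664, 0.00298 with the block).

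Ventral neural tube genes were lower in BRE_active cells by camera (adjusted p = 1.33e-06), with the adjusted p = 0.0695 with an estimated correlation. Of 8 measured members, 4 fell and 4 were not called, and 6 fell when adjusted over the list alone. The homeobox genes NKX6-2 and NKX6-1 had differences of -2.86 ± 0.27 (adjusted p = 0.000746) and -2.70 ± 0.41 (adjusted p = 0.00728). OLIG2, a determinant of motor neuron progenitors, had a difference of -2.14 ± 0.23 (adjusted p = 0.00137), and the floor plate gene FOXA2 one of -0.89 ± 0.17 (adjusted p = 0.0227). The globin level was lower on the same arrays, with a mean over 7 globin genes of 8.82 ± 1.41 (SD, n = 4) in BRE_active and 12.6 ± 0.667 in BRE_inactive cells.

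Of 6 measured genes of dorsal interneuron progenitors, 2 fell and 4 were not called. Adjusted over the list alone 5 fell, and 4 fell with the block. Camera gave the list an adjusted p of 3.86e-05, and the adjusted p = 0.173 with an estimated correlation. DBX2, a homeobox gene of the intermediate neural tube, had the smallest adjusted p of the named genes, 0.000172, with a difference of -2.27 ± 0.16. NHLH1 had one of -1.18 ± 0.22 (adjusted p = 0.0219). BHLHE22 differed by -1.25 ± 0.34 (adjusted p = 0.0944, 0.00119 with the block) and NEUROG1 by -0.08 ± 0.13 (adjusted p = 0.787).

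Of 14 measured neural progenitor genes, 2 fell and 12 were not called, 1 rose and 5 fell when adjusted over the list alone, and 2 rose and 6 fell with the block. By camera the adjusted p was 0.0175, and the adjusted p = 0.392 with an estimated correlation. SOX3 and PAX6 had differences of -1.09 ± 0.11 (adjusted p = 0.00137) and -1.11 ± 0.21 (adjusted p = 0.0206). SOX1 differed by -0.84 ± 0.20 (adjusted p = 0.0576, 0.0238 with the block), and SOX2 by -0.38 ± 0.20 (adjusted p = 0.359), or by -0.167 without BRE_inactive 2 (adjusted p = 0.473). Of 14 measured Notch genes, 1 fell and 13 were not called, 2 fell when adjusted over the list alone, and 4 fell with the block. The camera adjusted p was 0.0203, and the adjusted p = 0.173 with an estimated correlation. HES6 had a difference of -1.06 ± 0.18 (adjusted p = 0.0114). The Notch effector HES5 and the ligands DLL1 and JAG1 differed by -0.80 ± 0.26, -0.69 ± 0.24 and -0.66 ± 0.18, with adjusted p = 0.163, 0.183 and 0.0955, which became 0.0306, 0.0252 and 0.0447 with the block.

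Of 26 measured genes of neuron differentiation, 3 fell and 23 were not called. Adjusted over the list alone 2 rose and 6 fell, with the block 2 rose and 5 fell, and the camera adjusted p was 0.227. The cytoskeletal genes STMN2, NEFM and NEFL had differences of -1.19 ± 0.17, -1.02 ± 0.19 and -1.10 ± 0.22, with adjusted p = 0.00501, 0.0199 and 0.0293. Another well-detected NEFM probe set gave -0.57 ± 0.23 (adjusted p = 0.316). SLIT2 differed by 1.28 ± 0.30 (adjusted p = 0.0587, 0.0185 with the block), and TUBB3 by -0.34 ± 0.32 (adjusted p = 0.607).

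Genes of red blood cells made up most of the 12 largest decreases. Of 18 measured blood and endothelial genes, 5 fell and 13 were not called, 2 rose and 8 fell when adjusted over the list alone, and 1 rose and 6 fell with the block. Camera gave the list an adjusted p of 0.0175, 0.0523 with the block, and the adjusted p = 0.434 with an estimated correlation. The members that fell were all globins: HBBA (-5.83 ± 0.94, adjusted p = 0.00999), HBZ (-4.50 ± 0.64, adjusted p = 0.00531), HBBR (-4.30 ± 0.70, adjusted p = 0.0103), HBAD (-3.94 ± 0.73, adjusted p = 0.0198) and HBA1 (-3.45 ± 0.71, adjusted p = 0.0323). SLC4A1, the anion exchanger of the red cell membrane, was present on 4 BRE_inactive and 0 BRE_active arrays and was at least 13.0-fold lower (adjusted p = 0.0104). The erythroid membrane gene TSPO2 and the mitochondrial iron importer SLC25A37 had differences of -4.07 ± 0.62 (adjusted p = 0.00728) and -3.66 ± 0.76 (adjusted p = 0.0339). TUBB1 and LGALSL2 had differences of -3.47 ± 0.75 and -3.43 ± 0.64, with adjusted p = 0.0388 and 0.0202.

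**Figure D3:**
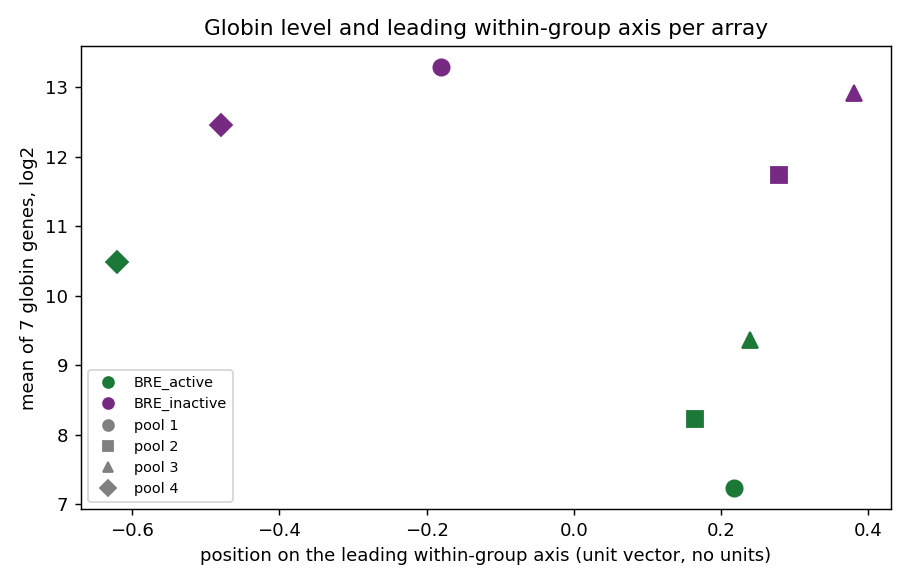
Mean log2 value of 7 globin genes (y axis) against the position of each array on the leading axis of the within-group deviations (x axis, no units). Points are the 8 arrays, with colour for reporter state and shape for embryo pool. BRE_active arrays lie between 7.23 and 10.5, below all BRE_inactive arrays at 11.7 to 13.3, and both pool 4 arrays lie far to the left.

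Markers of the other cell types that a neural tube dissection can carry showed few calls with all arrays. Of 16 measured surface ectoderm genes 1 rose (1 adjusted over the list alone), DLX5, which is also a BMP response gene, and the camera adjusted p was 0.509. EPCAM, CLDN1 and KRT14 differed by -0.74 ± 0.27, -1.04 ± 0.49 and -0.42 ± 0.22, with adjusted p = 0.201, 0.32 and 0.369, and without BRE_active 1 by -0.488, -0.622 and -0.235, with adjusted p = 0.375, 0.596 and 0.649. Limma called 0 of 16 somite and mesoderm genes (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 higher with the block), and the camera adjusted p was 0.131. MEOX1, PRRX1, MEOX2 and FOXC2 differed by 0.71 ± 0.28, 0.90 ± 0.42, 0.65 ± 0.34 and 0.86 ± 0.51, with adjusted p = 0.235, 0.313, 0.363 and 0.417, and MEOX2 had 0.0432 with the block. These genes depended on BRE_active 1 as well: without it the mean of the list went from 0.275 to 0.496, with a camera adjusted p of 4.19e-06 and the adjusted p = 0.111 with an estimated correlation. Limma then called 3 of the 16 higher, PRRX1, MEOX2 and LUM, a matrix proteoglycan gene named after its value was seen, by 1.41 ± 0.151, 1.03 ± 0.199 and 1.11 ± 0.22, with adjusted p = 0.00424, 0.0415 and 0.0455. BRE_active 1 was singled out because the list mean was low on it (4.64 against 5.47 to 5.57 on the other BRE_active arrays). A higher mean without it had to follow, so these values are no separate evidence of a rise. Of 6 notochord genes 0 were called (1 rose adjusted over the list alone and with the block, 1 at an unadjusted p under 0.05), and the camera adjusted p was 0.522. TBXT differed by 0.91 ± 0.25 (adjusted p = 0.0947, 0.000425 with the block), NOTO and COL2A1 by -0.12 ± 0.09 and 0.16 ± 0.15, with adjusted p = 0.551 and 0.609, and SHH was called present on 0 arrays (adjusted p = 0.539).

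Genes of DNA replication were lower as a list by camera (adjusted p = 0.0175), with the adjusted p = 0.392 with an estimated correlation. Limma called 0 of 21 measured members (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 2 lower with the block). MCM6, PCNA, TYMS and POLA1 differed by -0.52 ± 0.15, -0.43 ± 0.15, -0.25 ± 0.09 and -0.30 ± 0.12, with adjusted p = 0.112, 0.185, 0.188 and 0.261, and with the block MCM6 and PCNA had 0.0117 and 0.029. Limma called 0 of 25 genes of G2 and mitosis (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 lower with the block), and the camera adjusted p was 0.657. BIRC5, CENPE, KIF11 and CCNA2 differed by -0.43 ± 0.13, 0.43 ± 0.19, -0.21 ± 0.10 and -0.19 ± 0.10, with adjusted p = 0.128, 0.289, 0.307 and 0.357, and BIRC5 had 0.0469 with the block. Other probe sets, present on all arrays, had the opposite sign for CENPE (-0.264 ± 0.144, adjusted p = 0.454) and KIF11 (0.464 ± 0.221, adjusted p = 0.391). Of 11 cell cycle inhibitors BTG1 fell, with a difference of -0.59 ± 0.13 (adjusted p = 0.0472), 2 rose and 4 fell when adjusted over the list alone, 2 rose and 3 fell with the block, and the camera adjusted p was 0.579. CDKN1A, BTG2 and CCNG1 differed by 0.75 ± 0.17, -0.41 ± 0.10 and 0.39 ± 0.12, with adjusted p = 0.0537, 0.0543 and 0.131, which became 0.00465, 0.025 and 0.0222 with the block.

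Of 8 measured genes of the Sonic hedgehog response SCUBE2 fell, with a difference of -0.64 ± 0.14 (adjusted p = 0.044), 1 rose and 1 fell when adjusted over the list alone, as with the block, and the camera adjusted p was 0.227. DISP1 differed by 0.60 ± 0.16 (adjusted p = 0.0874, 0.00541 with the block), and GLI1 was called present on 0 arrays (adjusted p = 0.269). Of 19 measured genes of fibroblast growth factor and retinoic acid signalling STRA6, a retinol transporter, rose by 0.77 ± 0.10 (adjusted p = 0.00364), 1 rose when adjusted over the list alone, and the camera adjusted p was 0.146. ALDH1A2 and DUSP6 differed by 0.91 ± 0.36 and 0.23 ± 0.12, with adjusted p = 0.242 and 0.356, and SPRY1 was called present on 0 arrays (adjusted p = 0.314). Of 25 Hox genes 0 were called (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 higher and 2 lower with the block), and the camera adjusted p was 0.933, with a mean above 0 and a median below it. HOXD11 was present on 4 BRE_active and 0 BRE_inactive arrays (adjusted p = 0.297). HOXB4, HOXA6 and HOXD13 differed by -0.39 ± 0.10, -0.55 ± 0.20 and 0.17 ± 0.07, with adjusted p = 0.0766, 0.2 and 0.284, and with the block HOXB4 and HOXA6 had 0.0376 and 0.0125.

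Limma called 0 of the 19 stress and dissociation genes, 13 interferon genes and 15 apoptosis genes. At an unadjusted p under 0.05 there were 5, 3 and 2, and adjusted over the list alone 2 rose and 1 fell, 1 rose and 1 fell, and 1 rose. With the block 3 rose and 1 fell, 2 rose and 1 fell, and 1 rose. The 3 lists had camera adjusted p of 0.131, 0.933 and 0.794. HMOX1, present on 1 BRE_inactive array and 0 BRE_active arrays, was not called (adjusted p = 0.0719), and was called lower with the block (adjusted p = 0.000288). With so few present calls, no size of its difference is given. ATF3, present on 3 BRE_active and 0 BRE_inactive arrays, was not called (adjusted p = 0.188), and with the block it was at least 1.47-fold higher (adjusted p = 0.00489). JUN and KLF6 differed by 0.57 ± 0.15 and 0.37 ± 0.10, with adjusted p = 0.0744 and 0.0856, and JUN had 0.00388 with the block. EIF2AK2 and MX1 differed by 0.54 ± 0.14 and 0.36 ± 0.14, with adjusted p = 0.0796 and 0.219, and with the block 0.023 and 0.0379. IFIH1 and IRF1 were called present on 0 arrays, with adjusted p = 0.0955 (0.0319 with the block) and 0.374. CASP6, CASP8, CASP9 and MCL1 differed by 0.45 ± 0.11, 0.31 ± 0.13, 0.16 ± 0.08 and -0.18 ± 0.10, with adjusted p = 0.055, 0.252, 0.366 and 0.387, and CASP6 had 0.0121 with the block.

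Of the 25 lists, camera called 12 with the preset correlation, 11 with the block, and 0 with an estimated correlation (7 at an unadjusted p under 0.05). Leaving out single pools or arrays ended the camera call of the Wnt target, Notch, neural progenitor, replication and blood and endothelium lists in at least 1 case. The fry test, which asks whether the genes of a list move on balance one way, called 7 of the same 12. Its adjusted p was 0.000908 for BMP response, 0.000908 for neural crest, 0.00102 for Wnt target and 0.00176 for ventral neural tube genes. It was 0.0034 for dorsal neural tube and roof plate, 0.00808 for dorsal interneuron progenitor and 0.0213 for Notch genes. Of the 127 named genes 61 were called, 33 higher and 28 lower, and a further 31 were called with the block.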

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

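The tests of RNA integrity and of red blood cells in this part were chosen after the values they measure had been seen, and that of gene length before. A value was set apart here where, among the 4 arrays of a group, the gap between an extreme array and its neighbour relative to the range exceeded Dixon's 95% critical value. Chance gives such a gap in about 1 of 20 groups, and 16 of 304 groups of gene values and list means had one, against 15 by chance, so their number is close to that of chance.

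In pool 4, the BRE_active array was low for EDNRB (6.84 against 7.36 to 7.41 on the others) and NID1 (8.97 against 9.89 to 10.1), and high for CASP9 (7.80) and for the mean of the replication genes (9.64). The BRE_inactive array of pool 4 was low for CLDN1 (7.82 against 9.27 to 9.50) and for the mean of the BMP response genes (7.35), and high for HMOX1 (6.74 against 5.84 to 5.88). BRE_active 1 was low for ALDH1A2 (7.47 against 9.06 to 9.25), PRRX1 (6.92 against 8.87 to 9.07), the mean of the somite and mesoderm genes (4.64 against 5.47 to 5.57) and the mean of the Hox genes (6.12). BRE_inactive 2 was high for NEFL (7.08 against 6.16 to 6.28) and the mean of the cell cycle inhibitors (7.97), and low for SPRY1 (3.23). DUSP6 was high on BRE_inactive 3 (6.88 against 6.57 to 6.58), and CCNA2 was low on BRE_active 3 (8.61).

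Both arrays of pool 4 and, less so, BRE_inactive 1 stood apart on the leading axis of the within-group deviations, which held 55.9% of the within-group variance, with positions of -0.62, -0.479 and -0.18. Lower RNA integrity is argued against for pool 4: the mean difference between 3-prime and 5-prime signal of 3 control genes was smaller on both its arrays than on the other arrays of their groups, by -0.615 on average against an SD of 0.214 within groups. For BRE_inactive 1, which differed from the others of its group by 0.0117, lower RNA integrity stays open. On both arrays of pool 4 the signal did differ, in the other direction, so only lower integrity is addressed. A difference in RNA integrity in that other direction stays open for pool 4. Red blood cells stay open: the globin mean was the highest of its group on BRE_active 4 (10.48 against 7.23 to 9.36) and on BRE_inactive 1 (13.29 against 11.74 to 12.91), while that of BRE_inactive 4 was below that of BRE_inactive 3 by -0.467. Gene length stays open too: across genes, which are not independent replicates, the loading on the axis correlated with genomic length (Spearman correlation 0.409), so longer genes may be lower on these arrays for a technical reason such as labelling. No biological explanation was tested, and a difference in cell makeup of pool 4 remains open too.

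Of 57 reporter control probe sets on the array, outside the genes analysed, 1 was called: RPTR-Gga-U43284-1_s_at was higher in BRE_active cells by 3.18 on the log2 scale (adjusted p = 0.0031). With the pool as a block 2 more were called, RPTR-Gga-AF062997-1_at, higher by 1.156 (adjusted p = 0.135, 0.0188 with the block), and RPTR-Gga-AY342347_at, higher by 0.6155 (adjusted p = 0.076, 0.0192 with the block), each with 1 sign in all 4 pools. The sources used here do not say which reporters they hold.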

How the results depend on the processing

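The axis covariate, the present filter and the setting without pool 4 and BRE_inactive 1 were chosen after seeing the data. All 61 called named genes kept their direction in every setting in which they were tested, and 16 stayed past the threshold in all of them: EDNRB, DLC1, COL9A3, SOX10, PPP1R1C, MSX2, DLX5, BMP5, RSPO3, LMO4, COL9A1, NOTUM, SOX3, DBX2, NKX6-2 and OLIG2. ID1 ranged from -0.893 to -0.636, with adjusted p from 0.00148, with the axis covariate, to 0.253. DACT2 ranged from 1.22 to 1.89, with adjusted p from 7.25e-05 to 0.0508. BMP7, COL1A2 and BTG1 each lost their call in 12 of 24 settings.

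With the replicate block, 2156 probe sets and 1215 genes were called in place of 517 and 397, and with a random block 1068 and 751, and all of the 517 and 397 were among them. The block ended the call of the blood and endothelium list (adjusted p = 0.0523) and of none of the 61 named genes, and added 31 named genes. Array weights gave 1040 and 677, the axis covariate 3378 and 1761, and leaving out pool 4 and BRE_inactive 1 gave 1098 and 642. At least 2-fold left 234 and 169, and an adjusted p of 0.01 left 160 and 157. Leaving out 1 pool or 1 array gave 77 to 1419 probe sets, 135 to 809 genes and 8 to 12 lists. The lowest counts of probe sets and genes came without pool 3, the highest without BRE_active 4, and the fewest lists without pool 2. The cause of these changes was not tested, except that a stricter threshold leaves fewer calls. The axis covariate was taken from the same within-group deviations and is centred in each group. By construction it lowers their spread without moving a difference, so its higher counts are no support for the calls. Of the 12 lists, 0 were called with an estimated correlation and 7 with fry.

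Some list means and genes near 0, none of them called, changed sign. G2 and mitosis genes went to 0.00575 with centred medians and 0.000372 with array weights. Hox genes went to -0.00934 with quantile normalization, -0.0247 with the mean of probe sets, -0.000927 with the present filter and -0.00799 without pool 4 and BRE_inactive 1. Interferon genes went to 0.00274 with quantile normalization, 0.0166 with centred medians, 0.0394 with the dim filter, 0.02 with the mean of probe sets and 0.233 with the present filter. Apoptosis genes went to -0.0223 with quantile normalization. Leaving out 1 pool or array gave -0.0391 to 0.00976 for G2 and mitosis, -0.0165 to 0.0567 for Hox, -0.245 to 0.114 for surface ectoderm, -0.0463 to 0.025 for interferon and -0.00195 to 0.0419 for apoptosis genes, and -0.0792 to 0.238 for PAX3 and -0.181 to 0.0243 for NEUROG1. With the mean of probe sets KIF11 went to 0.126, COL2A1 to -0.0136 and WNT1 to -0.0141, and PAX3 went to -0.0035 without pool 4 and BRE_inactive 1; the cause was not tested. Leaving out 1 array moved the difference of 21 of the 127 named genes by over 1.5 times, and 0 of the 21 were called with all arrays: CCNA2, CLDN1, COL2A1, DUSP6, EPCAM, FOXC2, HOXD11, IRF1, KRT14, MEOX2, NEUROG1, NOTO, PAX3, PAX7, POLA1, PRRX1, SHH, SOX2, SPRY1, TUBB3 and WNT1.

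The pseudocount was not run, because the values are log2 already, nor the random block for lists, which camera does not take, nor term enrichment. Probe sets present on no array, 47.7% of those tested, limit what can be said of DACT1, PAX3 and WNT1.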

Other observations

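The test of RNA quality, that of ID1 against globins and that of ID1 without 3 arrays were chosen after the values they measure had been seen. The count over all 35 splits, the bounds for the erythroid markers and the axis covariate for ID1 were written before. No prediction was written in advance for the splits that part all pairs or for the random lists. Of the 35 splits of the 8 arrays into 4 and 4, 2, the real one included, called at least as many probe sets as the real one, and 2 at least as many genes, so chance is not excluded by this count. The real split called 517 probe sets and 397 genes, and the highest other split 2535 and 1410. That split sets BRE_inactive 1, 2 and 4 with BRE_active 4 against the rest, several times the real count, which points to a structure of the samples. The numbers pair the arrays by embryos, and of the 8 splits that part all 4 pairs, the other 7 called 0 probe sets by limma with and without the block, against 2156 and 517 for the real one. At an unadjusted p under 0.05 without the block, the highest of the 7 had 1900 and the real one 5346. The real split is 1 of only 8, so this count cannot exclude chance at a level of 0.05 either. In the other 7 the difference between the groups adds to the spread within each side, which by itself lowers their calls.

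The globins HBBA, HBZ, HBBR, HBAD, HBA1 and HBB, with SLC4A1 and TSPO2, were lower on all 4 BRE_active arrays than on the BRE_inactive array of the same pool; HBB averaged 11.2 against 14.2. The mean difference between 3-prime and 5-prime signal of 3 control genes was larger in BRE_active cells in all 4 pools, by 0.334 on average, which goes with lower RNA quality there. The labels also give different minimum cell numbers per pool, 100000 red and 20000 green cells. An effect of cell number was not tested and cannot be told apart from reporter state. Whether a general loss of RNA quality is the whole cause was not decided. Among 274 abundant probe sets outside the globins and erythroid markers the largest fall was -0.622 and the median -0.0208, against -2.97 for HBB. These probe sets were chosen for a mean log2 value above 12, which can leave out ones that fell strongly. Array medians lay between 4.24 and 4.32 after an unknown normalization, so a general loss may already have been removed from these values. Red blood cells in the BRE_inactive fraction are a candidate source, although sorting on the red marker of electroporated cells would be meant to remove them. Of 41 erythroid markers other than globins, 15 were present on all BRE_inactive arrays and had not been looked at, and their median was -0.234 (quartiles -1.03 and -0.0912), between the bounds of -0.3 and -0.1 set in advance, so the test does not decide. Of the 15, 13 were lower, which goes with red blood cells, and 0 were called higher and 2 lower: CA2 (-1.68 ± 0.22, adjusted p = 0.00364) and FAM210B (-1.15 ± 0.248, adjusted p = 0.0388), named after their values were seen. TAL1 had been seen and was left out; with it the median was -0.293, and 0.09% of 10000 random lists matched on level had a median as low as -0.234, while all 15 markers were also present on all BRE_active arrays.

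ID1 was lower in BRE_active cells although ID2 and ID3 were higher. The 3 arrays that stand apart, both of pool 4 and BRE_inactive 1, are argued against as its cause, since without them the difference was -0.731 (adjusted p = 0.0308, against 0.0487 with all arrays). The axis itself stays open: it is centred in each group, so as a covariate it cannot move a difference between the groups, which was -0.763 with and without it. Whether red blood cells that carry ID1 account for the lower ID1 was not decided. On the BRE_inactive array with the lowest globin mean, ID1 was higher than on the other 3 by 0.129. A value above their mean is what was written for the case without such cells. The gap was less than their SD of 0.39 and rests on a single array. No biological explanation was tested.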
